A study of Sus scrofa with 24 samples.

How the data were processed

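RNA from longissimus dorsi muscle of 2 pig breeds was measured on 24 Affymetrix GeneChip Porcine Genome Arrays. The breeds were German Landrace (DL in the labels) and Pietrain (Pi), each sampled at 35, 63 and 91 days post conception (dpc) and as adults, with 3 RNA pools, named a, b and c, in each of the 8 groups. Per the labels, total RNA was extracted with TRI Reagent, treated with DNaseI, cleaned on RNeasy columns, and turned into biotinylated cRNA from 500 ng. The number of animals in a pool, their sex and the adults' age are not given in the sources used here, so each p-value measures a difference against the spread between pools. The labels call the fetal pools peripubertal in a free-text field. Breed and stage were taken from the titles and the characteristics, which match. Only the titles of the 35 dpc pools carry a K, whose meaning was not known here.

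The deposited values are 1 log2 intensity per probe set and array. GCOS 1.1.1 is listed as processing software, and the method that summarised the probes and corrected for background is not given in the sources used here. The log base is not stated and was taken as 2 from the range of the values, 1.60 to 16.10, so every fold below rests on that reading. After sorting, all 24 deposited columns hold exactly the same values, with a median of 5.44, so the log2 table had been quantile-normalised across all arrays by the authors before deposit. Such a table cannot show a change in the total amount of mRNA, and each change is relative to the other probe sets on the array.

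Of the 24123 probe sets, 124 Affymetrix controls were left out and 23999 were tested. The array annotation gave exactly 1 gene symbol for 10069 of them, several for 198 and none for 13732. The 6765 different symbols include 2261 genes with more than 1 probe set, of which the probe set with the highest mean over the arrays stood for the gene. The background ceiling of each array was the highest of 23 control probe sets for which no target was spiked in, between 2.31 and 2.69. Where every array of one side of a comparison lay at or below its ceiling, the fold was computed against the ceiling and is given as a lower bound. A log2 change is a fitted value and is not exact where most pools of a group lay at background, as for FABP4, FABP7, HBE1, CCL21, NR4A3, POSTN, SLC2A4, CASQ2, AHSG, AFP, PPARG and MRC1.

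Every comparison used limma 3.58.1 in R 4.3.3. One model with a mean for each of the 8 groups was fitted to all 24 arrays, which leaves 16 residual degrees of freedom, and empirical Bayes moderation added 1.31 prior degrees of freedom. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets of a comparison, with a threshold of 0.05. Values after ± are standard errors from this fit. The 11 comparisons were the change between successive stages averaged over both breeds, Pi against DL at each stage and averaged over the 4 stages, and the interaction of breed with each step between stages. No batch or hybridisation date is given in the sources used here. The model assumes an equal spread in all groups, which the arrays do not show: the residual standard deviation per array was 0.235 to 0.309 at 35 dpc and 0.528 to 0.696 in adults.

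Choices made before the data were examined were the groups, the comparisons, the tests, the alternatives, 28 gene lists and the rule for named genes. The rule took, for each stage or breed comparison, the 10 largest rises and 10 largest falls among probe sets with 1 symbol that passed and whose pools did not overlap. For the interactions it took the 5 largest in each direction. It also took the 4 members of each list with the largest absolute change, and a fixed panel of muscle, growth and meat-quality genes. Of the panel, MYH1, MYH3, MYH4, MYH8, MYOG, PAX7, DLK1, H19, MB, COL1A1, MKI67 and ACTN3 had no probe set with that symbol.

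The lists covered sarcomere isoforms, contraction, metabolism, growth, protein turnover and markers of other cell types, and were written from textbook knowledge. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals, with p-values adjusted over the 27 lists that had at least 5 measured genes. Members were counted as passing over all probe sets and also adjusted over the list alone. The model was tested on simulated data with 200 changed probe sets per size, in which each probe set had its pooled spread in every group, so the larger spread of the adult arrays was not simulated. It recovered 49.5% of 2-fold and 79.5% of 4-fold changes for the breed comparison at 35 dpc, and 48.5% and 72% for that of adults. For 63 against 35 dpc it recovered 66% and 91%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

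RNA quality was read from the difference between 3' and 5' probe sets of the GAPDH and actin controls, compared between breeds by exact two-sided permutation. A score along the developmental change, set for each stage from the other stages, was compared in the same way; 3 against 3 arrays cannot give a p under 0.1. The alternatives were other between-array scalings, a filter on dim probe sets, an intensity trend with robust moderation, array weights, only the groups of a comparison in the fit, the pool letter as a replicate block, a 2-fold minimum, raised low values, and leaving out each pool. After the data were seen, a covariate for RNA quality, scaling to the hybridisation controls, fits in a single breed and removal of liver-type probe sets were added.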

Results

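The 24 arrays cover 8 groups of 3 pools, 1 group for each breed (DL and Pi) at 35, 63 and 91 dpc and in adults. Between 21.3% and 32.2% of the tested probe sets lay at or below the background ceiling of an array. Stage set the arrays apart on the first 2 principal components, which held 54.5% and 19.8% of the variance. Across probe sets, which are not independent replicates, the correlation between pools of a group was highest in DL at 35 dpc (0.990 to 0.992) and lowest in adult Pi (0.926 to 0.942). Adult Pi pools correlated with one another at a mean of 0.935 and with adult DL pools at a mean of 0.940, so they were no closer to each other than to the other breed. No array pair was identical. The number of arrays limits the precision of every value.

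**Figure D1:**
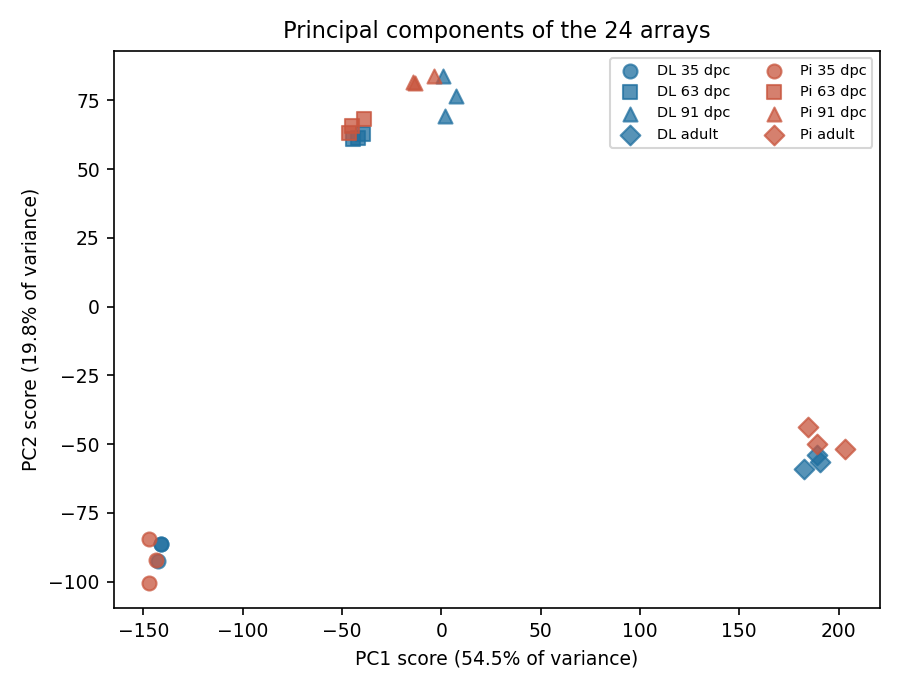
Scores of the 24 arrays on the first and second principal component, with the percent of variance on each axis; colour marks the breed and shape the stage. The stages form separate clusters along axes that hold 54.5% and 19.8% of the variance.

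The first comparison asked how the muscle samples changed between 35 and 63 dpc, averaged over both breeds. Genes of the contractile apparatus rose relative to the other probe sets. The share of muscle in the samples was not measured, so changes over this step were not separated from a change in tissue mix. All 9 measured fast sarcomere and fast-fibre genes passed as higher at 63 dpc, also adjusted over the list alone, with a median log2 change of 2.49 (camera adjusted p = 2.16e-09). MYOZ1, a Z-disc protein of fast fibres, rose by 5.12 ± 0.07, ATP2A1, the calcium pump of the fast sarcoplasmic reticulum, by 4.43 ± 0.12, MYH2, the fast IIa myosin heavy chain, by 3.77 ± 0.21, and TNNT3, fast troponin T, by 3.27 ± 0.07. Of 11 genes of calcium handling and excitation-contraction coupling, 10 rose and none fell, adjusted over all genes or over the list alone (median 2.74, camera adjusted p = 4.37e-07), among them the calcium release channel RYR1 (3.83 ± 0.12). Of 23 genes of sarcomere and Z-disc structure 18 rose and none fell, and 20 rose when adjusted over the list alone (median 1.32, camera adjusted p = 2.16e-09); XIRP1 rose by 5.41 ± 0.21, TMOD4 by 5.08 ± 0.20 and DES, desmin, by 3.08 ± 0.08. These 3 lists also passed with an estimated correlation (adjusted p = 0.00201, 0.00142 and 0.0119). Of 11 slow sarcomere and slow-fibre genes 9 rose and 1 fell by either adjustment (median 0.96, camera adjusted p = 0.000726); that call was lost with an estimated correlation (adjusted p = 0.103). MYH7, the slow myosin heavy chain, rose by 2.18 ± 0.06.

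Transcripts of nerve cells fell most between 35 and 63 dpc. Of 12 neural and Schwann cell markers 9 fell and 1 rose, adjusted over all genes or over the list alone, with a median log2 change of -6.82 (camera adjusted p = 2.16e-09; 0.00142 with an estimated correlation). NEFL, a neurofilament subunit, stood at 12.72 at 35 dpc and at 2.64 at 63 dpc. SNAP25, of the synaptic vesicle machinery, was at least 594.7-fold lower at 63 dpc, and RTN1 at least 641.3-fold lower. FABP7, a fatty acid binding protein of glia and neural progenitors, changed by -11.18 ± 0.08. Of 17 liver and plasma protein genes 0 passed in limma, in which 11751 of all probe sets had an unadjusted p below 0.05. HBE1, an embryonic globin, changed by -5.48 ± 0.13 and HBB by -1.79 ± 0.19.

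Markers of vessels rose over the same interval, and those of immune cells were called higher with the preset correlation alone. Of 19 endothelial markers 14 rose and none fell by either adjustment (median 0.99, camera adjusted p = 0.000726; 0.0191 with an estimated correlation), as did 8 of 11 smooth muscle and pericyte markers (median 1.13, camera adjusted p = 0.000726; 0.0278 with an estimated correlation). The smooth muscle members that rose most, SMTN (3.60 ± 0.08) and DES, are also expressed in skeletal muscle. CD74, the invariant chain of MHC class II, rose by 5.55 ± 0.16, and 13 of 33 immune cell markers rose and 1 fell by either adjustment (camera adjusted p = 0.0213; 0.103 with an estimated correlation). FABP4, a fatty acid binding protein of adipocytes and capillary endothelium, had the largest log2 rise of the named genes (6.50 ± 0.14, adjusted p = 3.69e-17); the 3 Pi pools at 35 dpc lay at background, so no fold is given. AGPAT2, of lipid synthesis, was at least 25.96-fold higher.

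Several metabolic lists rose between 35 and 63 dpc only with the preset correlation. These were fatty acid oxidation and uptake (22 of 30 rose and 2 fell by either adjustment, median 0.69, camera adjusted p = 0.000396; 0.103 with an estimated correlation), glycolysis and glycogen metabolism (14 of 26 rose and 4 fell by either adjustment, camera adjusted p = 0.0145; 0.134 with an estimated correlation) and oxidative phosphorylation and TCA cycle (49 of 77 rose and 13 fell, 51 and 16 adjusted over the list alone, median 0.37, camera adjusted p = 0.000836; 0.366 with an estimated correlation). CPT1B, which brings fatty acids into mitochondria, rose by 4.35 ± 0.22, and PYGM, muscle glycogen phosphorylase, by 3.60 ± 0.06. Collagens and extracellular matrix rose in 23 of 38 genes and fell in 3, or 4 adjusted over the list alone (camera adjusted p = 0.00162; 0.172 with an estimated correlation). Protein degradation and atrophy genes rose in 14 of 18 and fell in 2 by either adjustment (median 0.83, camera adjusted p = 0.00126; 0.0188 with an estimated correlation), with the muscle calpain CAPN3 at 3.65 ± 0.19. Cell cycle and DNA replication genes fell in 15 of 37 and rose in 1 by either adjustment (median -0.41, camera adjusted p = 0.00248; 0.0119 with an estimated correlation), TOP2A changing by -1.43 ± 0.16. Cytosolic ribosomal protein genes fell in 28 of 60 and rose in 6, or 34 and 6 adjusted over the list alone (median -0.15, camera adjusted p = 0.000542; 0.0228 with an estimated correlation). The imprinted growth factor IGF2 rose by 1.93 ± 0.10, the myogenic factors MYOD1 and MYF6 rose by 1.40 ± 0.20 and 2.72 ± 0.18, and MSTN, the growth inhibitor myostatin, changed by -1.72 ± 0.36.

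In all, 10611 of 23999 probe sets passed between 35 and 63 dpc, 5340 higher and 5271 lower at 63 dpc. As contrasts within a breed in the fit of all arrays, 7727 passed in DL and 8967 in Pi, 6037 of them in both and in the same direction and 53 in opposite directions. When arrays were scaled to their hybridisation controls, the median of all probe sets moved to -1.05 and 18905 passed. Of the named genes CAST, FABP3, TNNI1, RPS27L and EPCAM changed direction.

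Between 63 and 91 dpc, mitochondrial and fast-fibre genes rose together. Of 77 genes of oxidative phosphorylation and the TCA cycle, 57 rose and 1 fell, 60 and 2 adjusted over the list alone (median 0.45, camera adjusted p = 2.8e-23; 0.00936 with an estimated correlation). COX7A1, the muscle isoform of a cytochrome c oxidase subunit, rose by 3.95 ± 0.23, and SLC25A4, the muscle ADP/ATP carrier, by 1.27 ± 0.07. Of 30 genes of fatty acid oxidation and uptake 18 rose and none fell, 21 adjusted over the list alone (median 0.54, camera adjusted p = 5.51e-09; 0.0167 with an estimated correlation). They included PDK4, which holds back glucose oxidation (3.66 ± 0.30), and PPARGC1A, a coactivator of mitochondrial genes (2.45 ± 0.35). Of the 9 fast genes 6 rose and none fell, 7 adjusted over the list alone (median 0.47, camera adjusted p = 1.26e-07; 0.00541 with an estimated correlation), and MYH2 rose 28.8-fold (4.85 ± 0.21). Glycolysis and glycogen metabolism rose in 14 of 26 and fell in 4, 16 and 4 adjusted over the list alone (median 0.31, camera adjusted p = 2e-04; 0.03 with an estimated correlation). Calcium handling rose in 6 of 11 genes, or 8 with 1 falling adjusted over the list alone (median 0.63, camera adjusted p = 0.000205; 0.00817 with an estimated correlation).

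**Figure D2:**
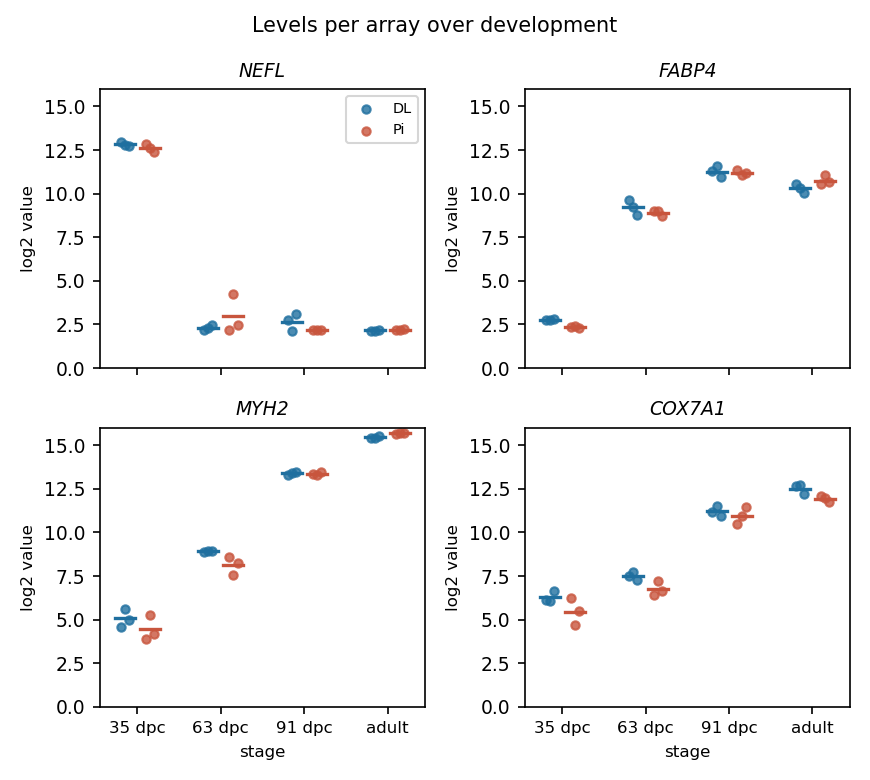
Deposited log2 values of 4 genes in each array by stage; points are the 3 pools of a group, lines their mean, and colour the breed. NEFL falls from 12.72 at 35 dpc to 2.64 at 63 dpc, while FABP4, MYH2 and COX7A1 rise at 63 or 91 dpc in both breeds.

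Vessel markers rose again between 63 and 91 dpc, and immune cell markers were called higher with the preset correlation alone. Of 19 endothelial markers 14 rose and none fell, 15 adjusted over the list alone (median 1.23, camera adjusted p = 5.51e-09; 0.000716 with an estimated correlation). Interferon and MHC class I genes rose in 11 of 25 and fell in 2 by either adjustment (median 0.45, camera adjusted p = 0.000466; 0.00541 with an estimated correlation), among them SLA-3 (2.70 ± 0.31) and SLA-2 (2.24 ± 0.18), porcine class I genes. Immune cell markers rose in 9 of 33 and fell in 1, 10 and 1 adjusted over the list alone (camera adjusted p = 0.00782; 0.0665 with an estimated correlation). The chemokine CCL21 had the largest rise, 6.47 ± 0.23, and KLF9, a hormone-responsive transcription factor, rose by 5.52 ± 0.28. ADIPOQ, the adipocyte hormone adiponectin, was at least 6.322-fold higher.

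Cell cycle genes fell between 63 and 91 dpc in 18 of 37 and rose in none, 21 adjusted over the list alone (median -0.71, camera adjusted p = 1.24e-08; 0.000123 with an estimated correlation), with TYMS, of thymidylate synthesis, at -2.11 ± 0.31. Of a list of 7 genes, embryonic and perinatal sarcomere isoforms with NCAM1 and CHRNA1, 4 fell by either adjustment (camera adjusted p = 0.0231; 0.151 with an estimated correlation), among them MYL4 (-1.76 ± 0.33), an embryonic myosin light chain, and TNNT2 (-1.25 ± 0.21), cardiac troponin T. MRLN, a micropeptide that regulates the calcium pump, changed by -5.05 ± 0.19 and CKB, brain creatine kinase, by -4.84 ± 0.21. Slow-fibre genes went both ways (2 rose and 6 fell of 11, 3 and 6 adjusted over the list alone, camera adjusted p = 0.0903; 0.493 with an estimated correlation). Sarcomere and Z-disc genes rose in 11 of 23 and fell in 1 by either adjustment (camera adjusted p = 0.000792; 0.123 with an estimated correlation). Immediate early and heat shock genes rose in 13 of 32 and fell in 3, 16 and 5 adjusted over the list alone (camera adjusted p = 0.00118; 0.306 with an estimated correlation), and clock and hormone responsive genes in 6 of 11 with 1 falling by either adjustment (camera adjusted p = 0.0463; 0.0881 with an estimated correlation). Ribosomal protein genes fell in 7 of 60 and rose in 1, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0248; 0.137 with an estimated correlation), and liver genes fell in 2 of 17, 1 adjusted over the list alone (camera adjusted p = 0.0231; 0.628 with an estimated correlation). In all 4389 probe sets passed, 2132 higher and 2257 lower at 91 dpc. As contrasts within a breed in the fit of all arrays, 2603 passed in DL and 2778 in Pi, 1407 in both and in the same direction and 13 in opposite directions.

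From 91 dpc to the adult, dividing cells and matrix receded and the glycolytic programme grew. Cell cycle genes fell in 31 of 37 and rose in 1, 32 and 1 adjusted over the list alone (median -2.49, camera adjusted p = 1.96e-11; 1.76e-05 with an estimated correlation). MCM2, of the replicative helicase, was at least 58.42-fold lower and TOP2A, a topoisomerase of dividing cells, changed by -6.28 ± 0.16. Collagen and matrix genes fell in 35 of 38 and rose in 1 by either adjustment (median -2.38, camera adjusted p = 3.72e-14; 0.00626 with an estimated correlation), with the matricellular protein POSTN at -9.80 ± 0.33 and the proteoglycan VCAN at -6.50 ± 0.48. Tendon and mesenchymal progenitor markers fell in 7 of 8 and rose in none by either adjustment (median -1.85, camera adjusted p = 0.00692; 0.0271 with an estimated correlation). Cytosolic ribosomal protein genes fell in 50 of 60 and rose in 2, 51 and 3 adjusted over the list alone (median -0.66, camera adjusted p = 4.22e-12; 0.000302 with an estimated correlation). Glycolysis and glycogen genes rose in 21 of 26 and fell in 4 by either adjustment (median 2.15, camera adjusted p = 2.52e-06; 0.0103 with an estimated correlation), among them SLC2A4, the insulin-regulated glucose carrier (4.90 ± 0.22), and PFKM, muscle phosphofructokinase (3.54 ± 0.13).

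Fetal muscle isoforms fell between 91 dpc and the adult. Of the 7 genes with embryonic and perinatal sarcomere isoforms, NCAM1 and CHRNA1, 5 fell and 1 rose by either adjustment (median -4.62, camera adjusted p = 0.0066; 0.106 with an estimated correlation). MYL4 changed by -8.14 ± 0.33, ACTC1, cardiac actin, by -4.62 ± 0.18, and NCAM1, a cell adhesion molecule, was at least 37.97-fold lower. Slow-fibre genes rose in 9 of 11 and fell in 2 by either adjustment (camera adjusted p = 0.00712; 0.188 with an estimated correlation), TNNT1, slow troponin T, by 1.63 ± 0.06, while CASQ2 changed by -5.57 ± 0.41. MYH2 rose by a further 2.19 ± 0.21. The mitochondrial uncoupling protein gene UCP3 had the largest rise, 7.60 ± 0.24, and PDK4 rose by 6.62 ± 0.30. With the preset correlation, fatty acid oxidation (20 rose and 3 fell of 30 by either adjustment, camera adjusted p = 0.00219; 0.167 with an estimated correlation), oxidative phosphorylation (46 and 11 of 77, 47 and 12 adjusted over the list alone, camera adjusted p = 0.0013; 0.283 with an estimated correlation) and adipocyte markers (14 and 3 of 24 by either adjustment, camera adjusted p = 0.024; 0.106 with an estimated correlation) were higher in adults.

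Growth and turnover genes shifted in the same interval. The insulin-like growth factor and imprinted gene list fell in 13 of 21 and rose in 4 by either adjustment (camera adjusted p = 0.0255; 0.117 with an estimated correlation), with IGF2 at -2.54 ± 0.10, PEG10 at -6.21 ± 0.18 and MEG3 at -6.10 ± 0.26. MYF5 changed by -4.35 ± 0.29, MYOD1 by -2.55 ± 0.20 and MSTN by -2.86 ± 0.36, while MYF6 rose by 2.74 ± 0.18. Protein degradation genes rose in 13 of 18 and fell in 3 by either adjustment (median 1.38, camera adjusted p = 0.00712; 0.0423 with an estimated correlation), FBXO32, a ubiquitin ligase of muscle atrophy, by 3.92 ± 0.17. Interferon and MHC class I genes rose in 18 of 25 and fell in none by either adjustment (median 1.63, camera adjusted p = 0.000885; 0.00661 with an estimated correlation), and clock and hormone responsive genes in 9 of 11 with 1 falling by either adjustment (median 1.73, camera adjusted p = 0.00361; 0.0166 with an estimated correlation). Immediate early and heat shock genes rose in 21 of 32 and fell in 2 by either adjustment (median 1.04, camera adjusted p = 0.000512; 0.206 with an estimated correlation), the nuclear receptor NR4A3 by 7.07 ± 0.37. Endothelial markers fell in 11 of 19 and rose in 2 by either adjustment (camera adjusted p = 0.0326; 0.125 with an estimated correlation), and smooth muscle markers in 7 of 11 with 1 rising by either adjustment (camera adjusted p = 0.0158; 0.117 with an estimated correlation). In all 13772 probe sets passed, 7394 higher and 6378 lower in adults. With the GAPDH 3' minus 5' value as a covariate, added after the data were seen, 5270 passed; that value was 0.56 and 1.03 in DL and Pi at 91 dpc and -0.42 and -0.59 in adults, so it moved with stage.

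**Figure D3:**
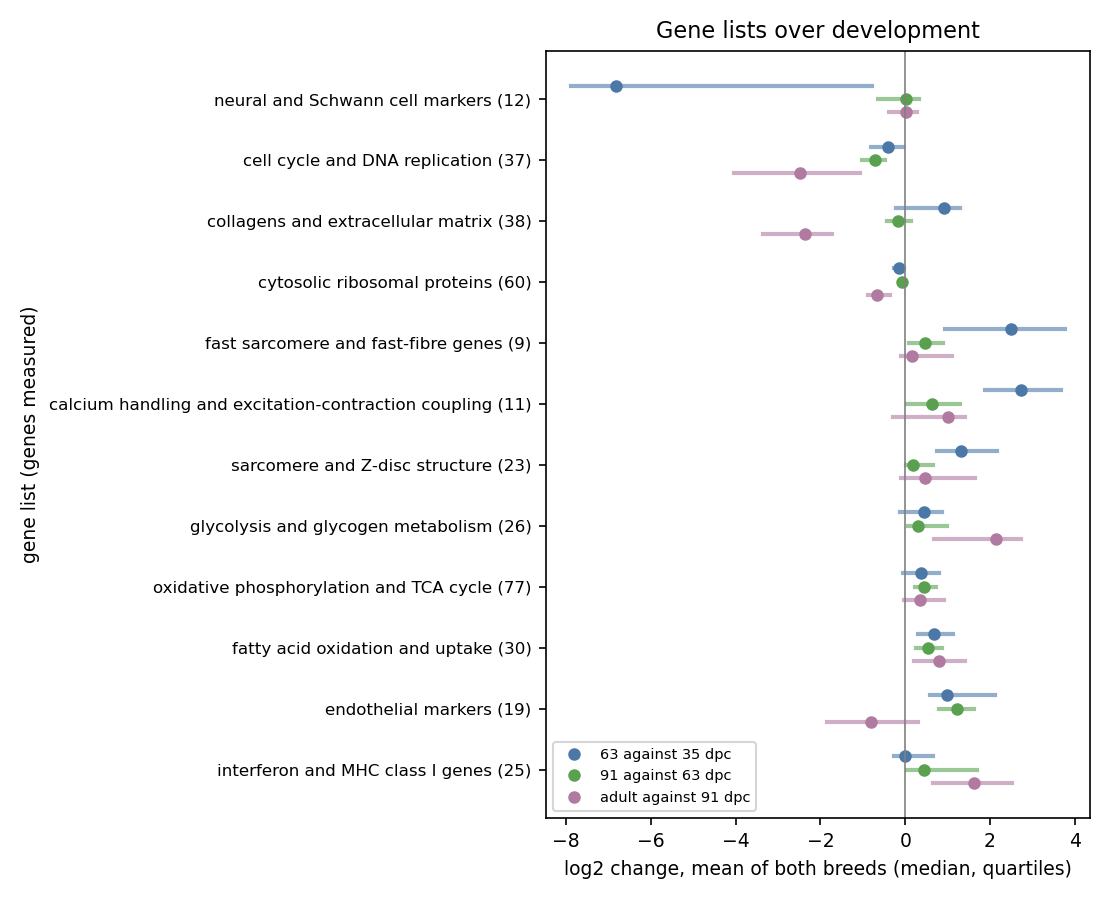
Median log2 change of the measured genes of 12 lists between successive stages, mean of both breeds; bars span the quartiles of the genes and numbers in brackets count them. Neural markers fall at 63 dpc (median -6.82) and cell cycle genes fall between 91 dpc and the adult (median -2.49).

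At 35 dpc the breeds differed in genes of muscle contraction. Of 11 genes of calcium handling and excitation-contraction coupling 5 were lower in Pi and none higher, 7 adjusted over the list alone (median -0.55, camera adjusted p = 5.95e-07; 0.00198 with an estimated correlation). They included ATP2A1 (-1.19 ± 0.17), CACNA2D1, a calcium channel subunit (-1.02 ± 0.15), and RYR1 (-0.89 ± 0.16). A second probe set of ATP2A1 did not pass (0.36, adjusted p = 0.82). Fast-fibre genes were lower in 3 of 9 and higher in none, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00521; 0.235 with an estimated correlation), with TNNT3 at -0.76 ± 0.10 and TNNI2, fast troponin I, at -0.70 ± 0.08. CKM, muscle creatine kinase, differed by -1.03 ± 0.10, PYGM by -1.26 ± 0.08 and MYH7 by -0.59 ± 0.09. The 35 dpc samples carried strong neural transcripts, and the share of muscle in them was not measured. A difference in tissue mix between the breeds was therefore not separated from a difference in these genes.

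Single genes differed more widely at 35 dpc. MMP14, a membrane metalloproteinase, was 14.1-fold higher in Pi (3.82 ± 0.51, adjusted p = 0.000262), TMEM38A, a potassium channel of the sarcoplasmic reticulum, at least 6.286-fold higher and TRO, trophinin, 7.16-fold higher (2.84 ± 0.24). TMOD3, a tropomodulin, was higher by 3.31 ± 0.82, while its second probe set did not pass (0.57, adjusted p = 0.36). IGF2R, which clears IGF2, was lower by -2.56 ± 0.41, LIMS2, an adaptor of integrin adhesion, by -2.02 ± 0.22, and HBE1 was also lower (adjusted p = 7.72e-06). In all 966 probe sets passed, 387 higher and 579 lower in Pi, with 3327 at an unadjusted p below 0.05. With only the 6 arrays of this stage in the fit 1008 passed, 414 of them shared, and 9 of the 20 largest named differences passed. MMP14 and IGF2R were among those that did not, TMOD3, TMEM38A, TRO, LIMS2 and HBE1 among those that did. With the GAPDH 3' minus 5' value as a covariate 18 of the 20 passed, and TMOD3 and MAPK8IP1 did not. At this stage the GAPDH 3' minus 5' value was 0.639 ± 0.145 (SD) in DL and 1.157 ± 0.0671 in Pi (exact permutation p = 0.1, the smallest possible), and that of actin 2.368 and 2.491 (exact permutation p = 0.4). The hybridisation controls were 8.96 and 8.36 and the poly-A controls, in the opposite direction, 5.909 and 6.912 (exact permutation p = 0.1 for each). Scaled to the hybridisation controls, the median of all probe sets moved to 0.61 and 9586 passed, 98.8% of them higher in Pi.

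At 63 dpc the largest differences between breeds lay in plasma protein genes of the liver. SERPINA1, alpha-1-antitrypsin, was at least 1592-fold lower in Pi (adjusted p = 0.0073), and the fetal plasma proteins AHSG and AFP were lower by -9.70 ± 1.74 and -6.99 ± 1.21, with 2 of the 3 Pi pools at background. In the 3 DL pools SERPINA1 was at 13.3, 11.8 and 13.8, and in Pi at 2.21 on average. Of the 17 genes of the liver list 3 passed as lower in Pi and none as higher, 6 adjusted over the list alone (median -2.57, camera adjusted p = 5.55e-08; 0.674 with an estimated correlation). These genes also varied within groups at other stages: ALB, albumin, was at 14.5 in adult Pi pool b and at 2.2 and 6.0 in pools a and c.

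FOS, an immediate early gene, was 7.57-fold lower in Pi at 63 dpc (-2.92 ± 0.32, adjusted p = 0.000572), and FBP2, a muscle enzyme of glycogen synthesis, 7.76-fold lower (-2.96 ± 0.27, adjusted p = 8.08e-05). Immediate early and heat shock genes were lower in 3 of 32 and higher in none, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0029; 0.674 with an estimated correlation). Erythroid markers were lower in 1 of 9, AHSP (-3.18 ± 0.68), and in 3 adjusted over the list alone (camera adjusted p = 0.00307; 0.0567 with an estimated correlation). Slow-fibre genes (1 of 11 lower, 3 adjusted over the list alone, camera adjusted p = 0.0341) and Z-disc genes (0 of 23 in limma by either adjustment, camera adjusted p = 0.0229) lost their calls with an estimated correlation (adjusted p = 0.674 for both). PCDH7, a protocadherin, was higher in Pi by 2.69 ± 0.49 and the antiviral gene MX1 by 1.96 ± 0.34. In all 329 probe sets passed, 161 higher and 168 lower in Pi, with 2959 at an unadjusted p below 0.05. With only the 6 arrays of this stage in the fit 11 passed, and of the 20 largest named differences SERPINA1 and FBP2; without DL pool a 163 passed.

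At 91 dpc oxidative, slow-fibre and immediate early genes were lower in Pi with the preset correlation. Oxidative phosphorylation and TCA cycle genes were lower in 9 of 77 and higher in none, 26 adjusted over the list alone (median -0.23, camera adjusted p = 5.87e-11; 0.211 with an estimated correlation), led by NDUFS6, a subunit of complex I (-1.58 ± 0.16). Without single pools 2 (without Pi b) to 19 (without DL c) of the 77 passed as lower. Slow-fibre genes were lower in 5 of 11 and higher in none, 9 adjusted over the list alone (median -0.39, camera adjusted p = 1.3e-08; 0.0795 with an estimated correlation), with SMTNL2 at -1.08 ± 0.19 and TNNI1, slow troponin I, at -0.33 ± 0.08. Without single pools 1 (without Pi a or b) to 6 (without Pi c) of the 11 passed, 2 without DL b and 3 without DL a. Fatty acid oxidation genes were lower in 4 of 30, 7 adjusted over the list alone (camera adjusted p = 0.000371; 0.307 with an estimated correlation). Immediate early and heat shock genes were lower in 9 of 32 and higher in 1, 12 and 1 adjusted over the list alone (median -0.46, camera adjusted p = 5.63e-05; 0.345 with an estimated correlation). FOS was 8.13-fold lower (-3.02 ± 0.32) and DUSP1, a phosphatase induced with it, differed by -1.15 ± 0.17. Endothelial markers were lower in 2 of 19, KDR (-2.69 ± 0.44) and AQP1 (-1.33 ± 0.28), and in 4 adjusted over the list alone (camera adjusted p = 0.00936; 0.189 with an estimated correlation). Glycolysis genes were lower in 2 of 26, 4 adjusted over the list alone (camera adjusted p = 0.0219; 0.307 with an estimated correlation), and SLC2A4 was at least 5.008-fold lower.

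Higher in Pi at 91 dpc were PCDH7 (3.32 ± 0.49), ADIPOQ (2.31 ± 0.53) and LOX, which crosslinks collagen (1.98 ± 0.38). In all 653 probe sets passed, 323 higher and 330 lower in Pi, with 3450 at an unadjusted p below 0.05. The GAPDH 3' minus 5' value was 0.561 ± 0.518 (SD) in DL and 1.033 ± 0.248 in Pi (exact permutation p = 0.3), with DL pool c at 1.16 among the Pi pools; for actin the difference was -0.032 (exact permutation p = 1). The poly-A controls (7.727 in DL, 6.8 in Pi) and the hybridisation controls (9.693 and 10.12) did separate the breeds (exact permutation p = 0.1 for each, the smallest possible). With the GAPDH value as a covariate 280 passed, and with only the 6 arrays of this stage 16. Without single pools the count ran from 248 (without Pi b) to 1257 (without DL c). Of the 20 largest named differences, 10 passed with the covariate and 2, FOS and POLR2E, with only the arrays of this stage. Scaled to the hybridisation controls the median of all probe sets moved to -0.42 and 5132 passed, 3.02% of them higher in Pi. Whether the change from 63 to 91 dpc in the oxidative list differed between breeds was not settled: 0 of 77 passed the interaction in limma, in which 2049 of all probe sets had an unadjusted p below 0.05 and which recovered 15.5% of simulated 1.41-fold changes, and the list's call (median -0.31, camera adjusted p = 2.88e-12) was lost with an estimated correlation (adjusted p = 0.235).

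**Figure D4:**
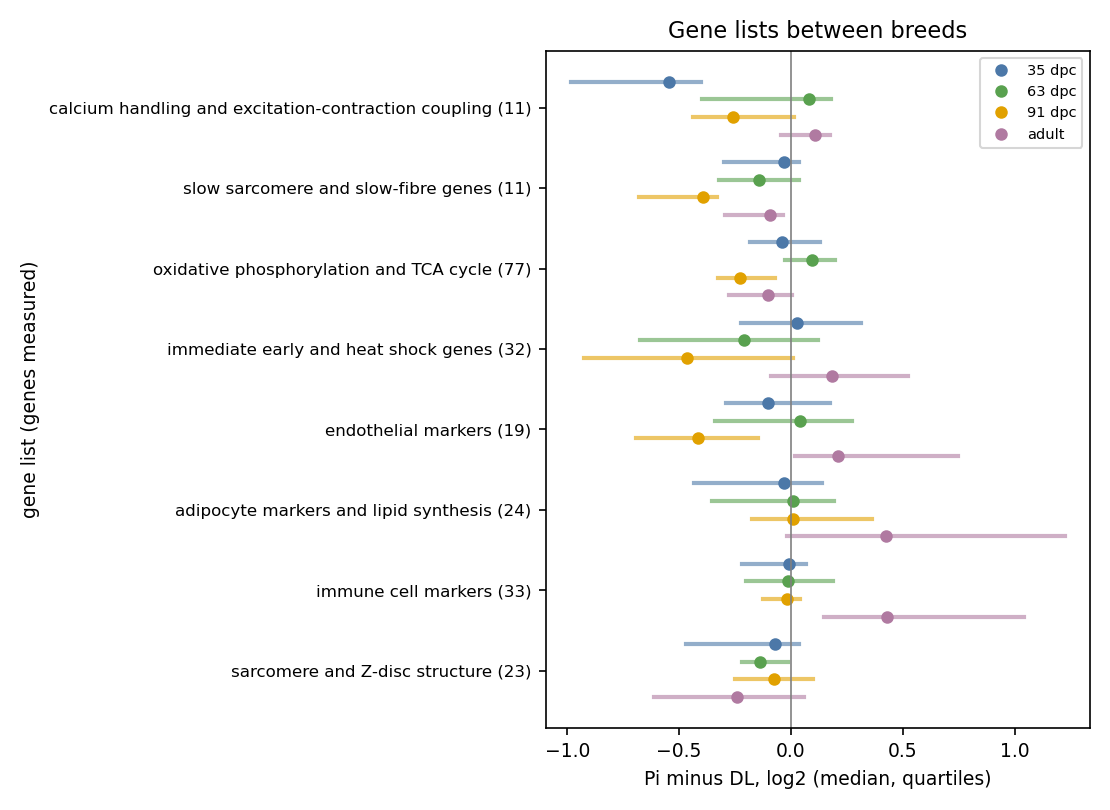
Median difference Pi minus DL (log2) of the measured genes of 8 lists at each stage; bars span the quartiles of the genes and numbers in brackets count them. Calcium handling genes have a median of -0.55 at 35 dpc, and slow-fibre genes one of -0.39 at 91 dpc.

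In adults, immune and adipocyte markers were called higher in Pi, in a group whose pools stood apart: pool b carried liver transcripts, among them the adipocyte list's RBP4 (11.54, group mean 5.29), and pool c scored 118.87 on the fourth principal component, against 7.27 and -16.78 for a and b. Of 33 immune cell markers 5 passed as higher and none as lower by either adjustment (median 0.43, camera adjusted p = 9.7e-05; 0.029 with an estimated correlation), including MRC1, a macrophage receptor (2.59 ± 0.44), and PTPRC, the leukocyte antigen CD45 (1.89 ± 0.39). Of 24 adipocyte and lipid synthesis genes 6 were higher and none lower, 6 and 1 adjusted over the list alone (median 0.43, camera adjusted p = 0.00208; 0.0478 with an estimated correlation). With an estimated correlation the immune list was not called without Pi b (median 0.466, adjusted p = 0.138) or Pi c (median 0.483, adjusted p = 0.0637). Of the single pools left out, only Pi a left the adipocyte list called (median 0.923, adjusted p = 0.0229). Without Pi b its median was 0.0572 (adjusted p = 0.138). PPARG, the regulator of fat cell formation, was higher (3.72 ± 0.49, adjusted p = 0.000174), with adult DL pools at 2.335, 2.6 and 2.317, close to or at background, so no fold is given, and CIDEA, of lipid droplets, was higher by 2.63 ± 0.62. The chemokine CCL19 was at least 8.517-fold higher and IGF2 was higher by 1.14 ± 0.15 (adjusted p = 0.000155).

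Structural and oxidative genes were lower in adult Pi with the preset correlation. Sarcomere and Z-disc genes were lower in 7 of 23 and higher in none, 9 adjusted over the list alone (median -0.24, camera adjusted p = 0.000546; 0.268 with an estimated correlation), with SMPX at -0.91 ± 0.10, ACTN2 at -0.75 ± 0.12 and DES at -0.68 ± 0.11. Oxidative phosphorylation genes were lower in 6 of 77, 10 adjusted over the list alone (camera adjusted p = 0.00292; 0.449 with an estimated correlation), and fatty acid oxidation genes in 7 of 30, 10 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0357; 0.433 with an estimated correlation). Slow-fibre genes (2 of 11 lower and 1 higher, 3 and 1 adjusted over the list alone, camera adjusted p = 0.0397; 0.433 with an estimated correlation) were also called lower. Called higher were ribosomal protein genes (5 of 60 higher and 1 lower, 8 and 1 adjusted over the list alone, camera adjusted p = 0.0357; 0.279 with an estimated correlation), endothelial markers (1 of 19 by either adjustment, camera adjusted p = 0.0397; 0.279 with an estimated correlation) and immediate early genes (2 of 32 by either adjustment, camera adjusted p = 0.0357; 0.449 with an estimated correlation). CASQ2, the calcium store protein of slow and cardiac muscle, was lower by -4.39 ± 0.58, but its second, dimmer probe set did not differ (0.00, adjusted p = 1). CAST, the calpain inhibitor, differed by -0.76 ± 0.14 and TNNI1 by -0.39 ± 0.08. EIF1AY, a gene of the Y chromosome, was lower by -4.53 ± 0.37, at 2.95 in adult Pi and 7.48 in adult DL; the sex of the animals is not given in the sources used here, so sex was not separated from breed in the adult comparison. The GAPDH 3' minus 5' value was -0.422 in adult DL and -0.588 in adult Pi and that of actin 2.319 and 2.523 (exact permutation p = 0.1 for each, the smallest possible). In all 1519 probe sets passed, 694 higher and 825 lower in Pi. With array weights, which give the scattered adult arrays less influence, 242 passed, and with only the 6 adult arrays 21. Of the 20 largest named differences 10 passed with array weights, and PPARG, MYBL2, EIF1AY, ST3GAL3 and SLC22A3 also with only the adult arrays.

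**Figure D5:**
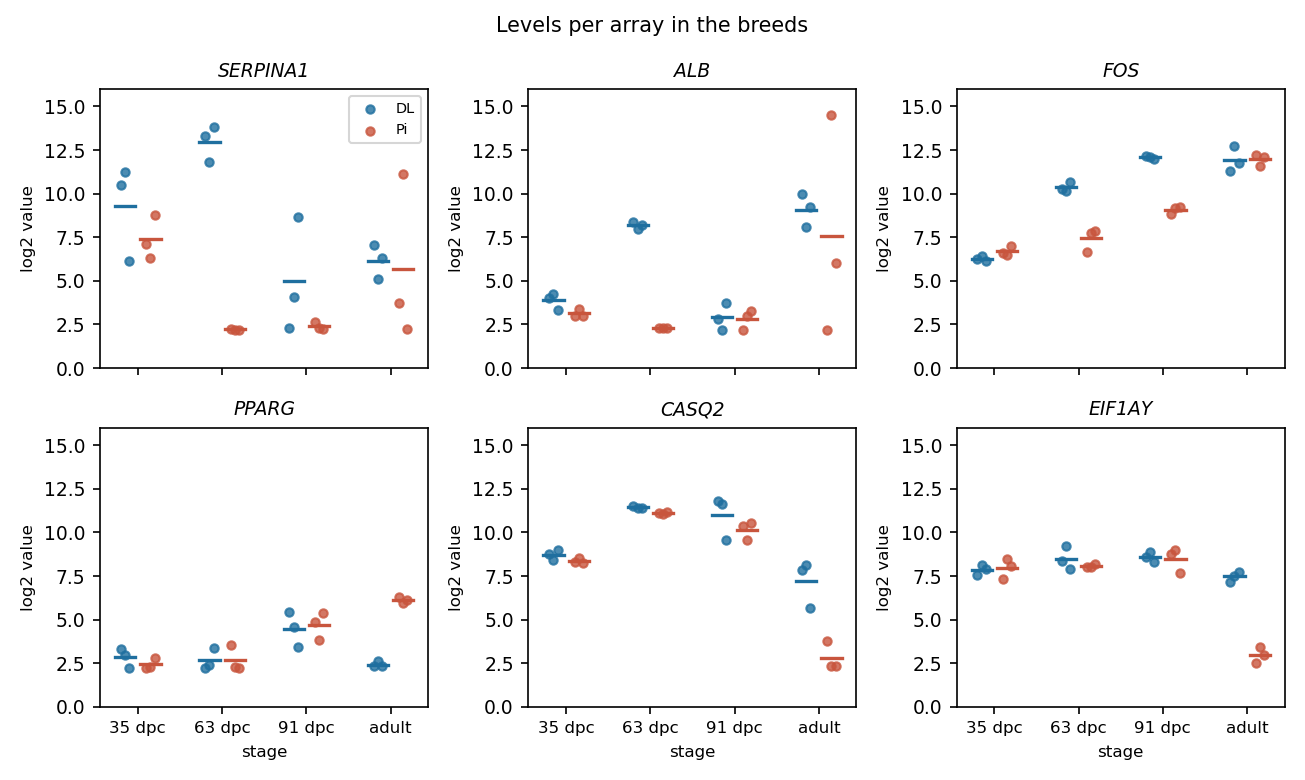
Deposited log2 values of 6 genes in each array by stage; points are the 3 pools of a group, lines their mean, and colour the breed. SERPINA1 averages 12.98 in DL and 2.21 in Pi at 63 dpc, and EIF1AY averages 7.48 in DL and 2.95 in Pi in adults.

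Averaged over the 4 stages, slow-fibre and Z-disc genes were lower in Pi with the preset correlation. Slow-fibre genes were lower in 7 of 11, 9 adjusted over the list alone (median -0.21, camera adjusted p = 7.51e-07; 0.113 with an estimated correlation), and Z-disc genes in 9 of 23, 11 adjusted over the list alone (camera adjusted p = 3.76e-05; 0.117 with an estimated correlation). Oxidative phosphorylation (10 of 77 lower and 2 higher, 13 and 2 adjusted over the list alone, camera adjusted p = 5.93e-05; 0.265 with an estimated correlation), glycolysis (4 of 26, 7 adjusted over the list alone, camera adjusted p = 0.00201; 0.117 with an estimated correlation) and calcium handling genes (2 of 11, 4 adjusted over the list alone, camera adjusted p = 0.00786; 0.113 with an estimated correlation) were called lower in the same way. MYH7 differed by -0.24 ± 0.05 and TNNI1 by -0.23 ± 0.04. ELOVL6, a fatty acid elongase, was higher in Pi by 0.85 ± 0.08 (adjusted p = 1.31e-05) and PCBP2, an RNA-binding protein, by 1.02 ± 0.10 (adjusted p = 1.42e-05). Of 246 probe sets that passed at 2 stages 170 had the same direction, of 41 at 3 stages 20, and of 9 at 4 stages 8, and PCBP2 was the only one of these 8 with a gene name; 2 other probe sets of PCBP2 did not pass (-0.16, adjusted p = 0.28, and -0.73, adjusted p = 0.46). MAPK9, a stress-activated kinase, was lower by -1.42 ± 0.25 and ARPC4, of the actin nucleating complex, by -0.87 ± 0.11. In all 1509 probe sets passed, 732 higher and 777 lower in Pi. Across probe sets, the breed differences at 63 and 91 dpc correlated at 0.329, with 38 passing as higher and 44 as lower at both stages, where 2.17 and 2.31 would fall together by chance, and 2 in opposite directions. The other 5 pairs of stages correlated at 0.00455 to 0.106. Higher at both, lower at both and opposite were 10, 10 and 31 for 35 and 63 dpc (2.6 and 4.05 by chance for the first 2 counts), 20, 22 and 27 for 35 and 91 dpc (5.21 and 7.96), 32, 22 and 38 for 35 dpc and the adult (11.2 and 19.9), 15, 10 and 6 for 63 dpc and the adult (4.66 and 5.78), and 46, 33 and 17 for 91 dpc and the adult (9.34 and 11.3). The chance counts take the stages as independent. All comparisons share the fitted spread of a probe set, so those with a small spread can pass at several stages in either direction. No chance count was computed for opposite directions, so a count above chance alone does not show agreement.

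The test of a different change between stages in the breeds passed for 793 probe sets from 35 to 63 dpc and 638 from 91 dpc to the adult. Without single pools these counts ran from 466 to 760 and from 353 to 945. With array weights, or with only the groups of the comparison in the fit, both moved by over 1.5 times, as given below. From 63 to 91 dpc 22 passed, a count that 9 of 100 splits of the arrays reached, the real one included. These splits shuffle the breed labels at each stage apart, so they do not test the interaction alone. Whether the count goes beyond chance was therefore not settled. From 35 to 63 dpc MMP14 rose by 3.88 in DL and changed by -1.46 in Pi. From 91 dpc to the adult PPARG changed by -2.06 in DL and 1.44 in Pi. No list passed an interaction with both the preset and the estimated correlation.

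A score along the developmental change asked whether a breed stood ahead of the other. At 91 dpc the Pi arrays scored lower by -0.195 than the DL arrays without overlap, on an axis 5.19 log2 units long (exact permutation p = 0.1, the smallest possible). At 35 dpc, 63 dpc and in adults the differences were 0.059, -0.013 and -0.0005 (exact permutation p = 0.2, 0.4 and 1), and the arrays overlapped. At 91 dpc the arrays also lay apart with 300 probe sets (-0.256), 3000 probe sets (-0.181) or the axis from Pi arrays (-0.232; exact permutation p = 0.1 for each), and overlapped with the axis from DL arrays (-0.148, exact permutation p = 0.2). Other axes separated the breeds at 63 dpc as fully, in opposite directions, so a separation of 3 against 3 arrays carries little weight.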

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

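Among the tests of this part, the second list of neural genes, the endothelial list, the adult Pi pool b profile and the slow-fibre part of the RNA quality test were chosen after the results were seen. Some readings were also made stricter after their values were seen, as given below.

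Some genes changed between stages differently in the 2 breeds, by a test of the interaction. From 35 to 63 dpc the change in Pi minus that in DL passed for 793 probe sets. It was positive for METTL22 (3.67, DL -2.86 and Pi 0.811), ST3GAL3 (3.46), GTPBP1 (2.96), CACNB3 (2.70) and CLN6 (2.45), and negative for MMP14 (-5.33, DL 3.88 and Pi -1.46), POLR2E (-4.51), TMEM38A (-4.15), FOS (-3.35, DL 4.08 and Pi 0.735) and AGT (-3.31). Of 100 splits of the arrays 1, the real one, gave as many, and the highest other gave 470. The splits shuffle the breed labels at each of the 2 stages apart. A split can thus keep the breed difference at 1 stage and reverse it at the other, which adds the 2 differences. The splits test for any breed difference at these stages. Their share does not decide on the interaction, here or in the later steps. From 63 to 91 dpc 22 passed, among them FBP2 (2.13), EIF3E (0.80), SLC2A4 (-2.68), AHCY (-1.36), WDR37 (-1.19) and LOC100522130 (-0.91). Here 9 of 100 splits gave as many, the highest 1179. As these splits do not decide on the interaction, whether the 22 go beyond chance was not settled. Why some splits called many times the real count was not tested. From 91 dpc to the adult 638 passed, with PRKCZ (4.25), HERC3 (3.87), CREB1 (3.82), CCL19 (3.64) and PPARG (3.50) positive and ST3GAL3 (-5.31), EIF1AY (-4.42), FAM234A (-3.96), ALCAM (-3.67) and CASQ2 (-3.56) negative. EIF1AY, of the Y chromosome, stood at 2.49, 3.41 and 2.95 in the adult Pi pools and at 7.18 or more in all other arrays. Sex was thus not separated from breed in this step. The second, dimmer probe set of CASQ2 did not differ between the adult breeds. Of 100 splits 2 gave as many, the real one included, and the highest other gave 1451. The cause of that larger count was not tested. For TMEM38A, AGT, SLC2A4, CCL19 and, in the last step, ST3GAL3, at least 1 group lay wholly at background, so the fitted values are not exact.

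The control probe sets were not used in the comparisons and carried signal. The array means of the poly-A controls ran from 5.66 to 9.74 and those of the hybridisation controls from 8.20 to 10.56. Groups of 3 pools were not tested for single distant arrays.

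The first pattern weighed is the neural signal at 35 dpc. A second list of neural genes had 25 measured genes, of which 18 fell by 63 dpc with a median of -2.17; without FABP7 and RTN1, already seen among the largest falls, 16 of 23 fell and 2 rose, with a median of -1.50 and quartiles of -4.90 and -0.21. The whole list met the bound set for neural tissue and the reduced list did not, so the test leaves neural tissue in the 35 dpc samples open. MAP2 changed by -7.08 and GAD1 by -6.18, which goes the way of neural tissue. VAMP2 (0.41) stood at 8.45 to 9.66 in every group, and NEUROD1 and LHX3 at 2.41 or below in every group. These members carry little information on neural tissue. A lower share of muscle at 35 dpc need not raise every other cell type there, and the endothelial list also rose at the next step. Its median change of 0.991 therefore does not decide on the share of muscle. The stage itself stays open as a biological explanation and was not separated from the mix of tissue in the 35 dpc samples.

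The second pattern is the liver transcripts of the DL pools at 63 dpc. Outside the liver list, 229 probe sets stood over 3 log2 units brighter in adult Pi pool b than in both other adult Pi pools. Other groups were not used in this choice. Their median Pi minus DL difference at 63 dpc was -0.0192 (quartiles -0.313 and 0.0814), against 0.0063 for all probe sets. A median as low, in the direction of liver RNA, arose in 1.32% of random sets matched on mean level. The random sets draw unrelated probe sets, while the 229 were chosen together from 1 array, so that share carries little weight. The median of the 229 met the bound set in advance against liver RNA, but the bound lies within the quartiles. The 67 of the 229 above 5 at 63 dpc had a median of 0.0519, against what liver RNA in DL predicts. These 67 went both ways (quartiles -0.586 and 0.471, with 2 passing as lower in Pi), so liver RNA in these pools was read as open. The test against the profile of adult Pi pool b took SERPINA1, the largest named fall of this comparison, as its reference. Of the 20 abundant probe sets of that profile, SERPINA1 stood highest in the DL 63 dpc pools relative to adult Pi pool b (1.84). That 16 of the 20 (80%) lay over 5 log2 units further below adult Pi pool b than SERPINA1 thus depends on this reference. The distances of the 20 varied (quartiles -7.59 and -4.07), and ALB averaged 8.19 in DL at 63 dpc, against 14.5 in adult Pi pool b. The DL pools thus did not hold that profile in its adult proportions, which does not decide on other liver RNA. Liver-type probe sets, 246 of the 23999 tested, were 1.52% of those passing at 63 dpc, so they did not make up the breed difference. They were taken from adult Pi pool b and the liver list, so their share does not decide on fetal liver as a source. Fetal liver RNA, or expression of these genes in DL muscle, stays open, as no fetal liver profile was used here.

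The third pattern is the lower oxidative and slow-fibre signal in Pi at 91 dpc. With the GAPDH 3' minus 5' value as a covariate the oxidative median moved from -0.23 to -0.139 (quartiles -0.293 and -0.0442) and the genes passing as lower from 9 to 2, and the list was called only with the preset correlation (camera adjusted p = 2.39e-05; 0.305 with an estimated correlation, and 0.211 without the covariate); the bound set in advance against RNA quality was met, but the upper quartile lies inside it, so RNA quality was read as open. For the slow-fibre part the median moved from -0.391 (quartiles -0.678 and -0.328) to -0.405 (quartiles -0.452 and -0.315). The genes passing went from 5 to 1 and the median standard error of the list from 0.0976 to 0.119. The list was called only with the preset correlation (camera adjusted p = 1.73e-07, and 0.168 with an estimated correlation, which was 0.0795 without the covariate). The covariate draws on differences between pools of a group, which were largest in DL at 91 dpc (SD 0.518). There pool c (GAPDH value 1.16) had a mean slow-fibre deviation of 0.0626 from the stage, against 0.345 and 0.385 in pools a and b. The Pi pools did not follow that order, so RNA quality was read as open for this part too. A later maturation of Pi may contribute, but the score does not decide on it. The Pi arrays lay behind the DL arrays by -0.1951 (exact permutation p = 0.1, the smallest possible), as with 300 or 3000 probe sets or the axis from Pi arrays (-0.2559, -0.1812 and -0.2321, without overlap). With the axis from DL arrays they overlapped (-0.1475, exact permutation p = 0.2). Oxidative and slow-fibre genes were not removed from the axis, so a lower score can restate the pattern. DL c, with its GAPDH value among those of Pi, also scored lowest in DL (0.038, against 0.107 and 0.148 for a and b). The score thus did not separate maturity from RNA quality. Neither RNA quality nor maturity is settled. The GAPDH value and actin did not separate the breeds (exact permutation p = 0.3 and 1), while the poly-A and hybridisation controls did (exact permutation p = 0.1 for each). Without DL c, whose GAPDH value lies among those of Pi, the oxidative median was -0.288 with 19 passing as lower.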

How the results depend on the processing

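The GAPDH covariate, the scaling to the hybridisation controls, the fits in a single breed, the removal of liver-type probe sets and the list tests without single pools or with the covariate were chosen after the data were seen. Quantile normalisation and median centring moved nothing, because the deposited table was already quantile-normalised, so they say nothing about stability. The filter on dim probe sets, the intensity trend with robust moderation and the removal of liver-type probe sets left each count within 1.5 times its value. The development counts moved by over 1.5 times under a 2-fold minimum, for 63 against 35 dpc with control scaling, for 91 against 63 dpc in a single breed and for adult against 91 dpc with the covariate. With only the arrays of the stage in the fit, which cuts the degrees of freedom as well as the pooled spread, the breed counts fell at 63 dpc, 91 dpc and in adults but not at 35 dpc (1008). Unless the construction of a setting shows the cause, as fewer arrays, the 2-fold minimum or an added scale do, the cause was not tested.

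With array weights the breed counts were 3156 (35 dpc), 1000 (63 dpc), 1285 (91 dpc) and 242 (adult), and the interactions 2329, 113 and 174 in order of stage. With only the groups of a comparison in the fit the breed counts were 11 at 63 dpc, 16 at 91 dpc and 21 in adults, and the interactions 1395, 7 and 80. With values below the 20th percentile raised to it the interaction of 91 against 63 dpc was 41. With the GAPDH 3' minus 5' covariate 5270 passed for adult against 91 dpc, 280 for breed at 91 dpc, 621 for the breed average, and 44 and 324 for the later 2 interactions; CORO1A reversed in adult against 91 dpc (-0.0073). With only the DL arrays 2331 and with only the Pi arrays 2387 passed for 91 against 63 dpc; CAST reversed in adult against 91 dpc in DL (0.059) and SERPINA1 in 91 against 63 dpc in Pi (0.173). With a 2-fold minimum the counts were 6154, 1686 and 8808 for the stages, 396, 179, 341 and 861 for breed by stage, 170 for the breed average and 486 for the first interaction.

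Scaled to the hybridisation controls 18905 passed for 63 against 35 dpc, 9586, 134 and 5132 for breed at 35, 63 and 91 dpc, 875 for the breed average, and 7367 and 298 for the first and last interaction. This scaling adds 1 value to each array and moved the median of all probe sets by -1.05, -0.189 and -0.234 for the stages and by 0.606, -0.103, -0.418 and -0.228 for breed by stage. Of 624 named results 537 kept their direction and side of the threshold, 72 missed the threshold and 15 reversed. Reversed for 63 against 35 dpc were CAST (-0.346), FABP3 (-0.182), TNNI1 (-0.671), RPS27L (-0.201) and EPCAM (-0.0953), and for adult against 91 dpc CKM (-0.0355) and TNNI2 (-0.157). Reversed between breeds were MYH7 (0.0117), DES (0.00623), PGAM2 (0.0710), RPLP2 (0.2205) and RPL27 (0.277) at 35 dpc, CAPN2 (-0.0358) and RPL13 (-0.0530) at 91 dpc, and MYH7 in the first interaction (-0.0615).

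With an estimated correlation 28 of 94 gene list calls passed, all of them among the 94. Without single pools the adult immune list had p = 0.0123 to 0.138 (above 0.05 without Pi b or c), the adult adipocyte list 0.0229 to 0.138 (below 0.05 without Pi a alone), and 0.0243 without RBP4, all with an estimated correlation. The breed difference along the developmental axis at 63 dpc was -0.0813 with 300 probe sets, 0.0195 with 3000, -0.0656 with the axis from DL arrays and 0.0712 with that from Pi arrays, and at 35 dpc 0.0941 with that from Pi arrays; all but that with 3000 separated the breeds without overlap (exact permutation p = 0.1), in opposite directions at 63 dpc. The pool letter as a replicate block gave 10578, 4368 and 13671 for the stages and 921, 281, 597 and 1490 for breed by stage; pools of the same letter in different groups correlated at -0.077 to 0.091 in their deviations, so the letters were not used as pairs.

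Leaving out each pool in turn, a leave-one-out range was 9942 to 10232, 3883 to 4228 and 13164 to 13965 for the stages, 581 to 846 (35 dpc), 163 to 388 (63 dpc), 248 to 1257 (91 dpc) and 1326 to 1900 (adult) for breed, 1160 to 1876 for the breed average, and 466 to 760, 12 to 115 and 353 to 945 for the interactions. Single pools moved breed counts by over 1.5 times: at 35 dpc to 629, 581 and 623 without DL a, b and c and 583 without Pi c; at 63 dpc to 163 and 176 without DL a and c and 192, 178 and 167 without Pi a, b and c; at 91 dpc to 293, 399 and 1257 without DL a, b and c and 248 without Pi b. They moved the first interaction to 524, 526, 510 and 519 without DL a, b and c and Pi c at 35 dpc and 466 without DL a at 63 dpc, the second to 48, 35 and 14 without DL b and c and Pi a at 63 dpc and 115, 12 and 74 without DL c and Pi b and c at 91 dpc, and the third to 353, 424 and 366 without DL a and Pi a and b at 91 dpc. Of 624 named gene results that passed, 526 passed in every such fit, 98 missed the threshold in at least 1 and 0 reversed.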

Other observations

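The splits were chosen in advance and none of the tests in this part was chosen after the results were seen. For 63 against 35 dpc, 1 of 100 splits of the arrays, the real one, gave as many passing probe sets (10611, highest other 6333). For 91 against 63 dpc it was 1 of 100 (4389, highest other 1002), for adult against 91 dpc 1 of 100 (13772, highest other 9124), and for the breed average 1 of 100 (1509, highest other 193). For these 4 counts the share of 1 of 100, the real split included, lay under the bound of 0.05 set in advance. The splits cannot test for a batch that follows stage or breed. At a single stage the 6 arrays make 10 splits, too few for a share under 0.05: 1 of 10 gave as many at 35 dpc (966, highest other 23), 63 dpc (329, highest other 3), 91 dpc (653, highest other 130) and in adults (1519, highest other 480).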
